A study of Mus musculus with 24 samples.

How the data were processed

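RNA was measured in the thoracic aorta of 24 mice, 6 in each of 4 groups formed by genotype (wild type, WT, or Klotho knockout, KO) and diet (0.05% or 0.48% magnesium by weight, called minimal and high). Per the labels, mice were fed from birth to 8 weeks of age, RNA was extracted with TRIzol without a DNase step, and library preparation was done by a sequencing company. Per the submitters' processing notes, Salmon and FastQC were used and the build was mm10, with no versions given. Each deposited table, per the file headers, held a length, an effective length, a TPM value and an estimated count of reads for 102919 transcripts of 41012 genes. The authors' estimated counts were the values tested, and the deposited TPM values were used only to weight transcript lengths in 1 alternative. Median effective length lay 249 bases below transcript length, and the effective lengths were the same in all 24 files. Such estimates split reads between transcripts and between near-identical genes by model, so the count of a gene with a close copy is uncertain.

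Genes in the tables carry Mouse Genomes Project identifiers of the C57BL/6NJ strain, while the build named by the notes is mm10. The files do not pair these identifiers with gene symbols, and 0 of the 41012 identifiers occurred in the gene name tables used here. No symbol was inferred. The lists of calcification, matrix, phosphate, magnesium and cell type genes fixed before the data were examined, the panel of named genes, the transcript of Klotho itself, the inference of sex and the covariates for fat and muscle are therefore not analysed here. The rule fixed for named genes needed symbols. In its place 4 identifiers are printed, the 2 with the smallest adjusted p among genes that rose in KO against WT mice on minimal magnesium and the 2 with the smallest adjusted p among genes that fell on high magnesium in KO mice, each with a mean of at least 1 CPM in a group compared. This reduction was made after the values were seen.

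Estimated counts were summed over the transcripts of a gene and rounded, which changed library totals by at most 0.0017%. Totals ran from 9947302 to 18926675 counts per library. In edgeR 4.0.16 (R 4.3.3, limma 3.58.1), genes passing filterByExpr (16741) were scaled by TMM, and 1 quasi-likelihood model with 4 group means and robust dispersion estimates gave all 6 comparisons. Adjusted p is from the Benjamini-Hochberg method within a comparison, and a gene is called below 0.05. The standard error of a log2 fold change is its size divided by the root of the quasi-likelihood F. Levels are CPM, the counts of a gene relative to the TMM-scaled library total, given as mean ± SD. Principal components used log2 CPM with a prior count of 2. The common biological coefficient of variation was 40.6%. Among all 276 pairs of the 24 libraries, chi-square per degree of freedom over genes with at least 20 counts in the pair ran from 13.38 to 357.6, so no library repeated another.

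On simulated counts with 200 changed genes of 16741, KO against WT on minimal magnesium returned 43% of 100 genes changed 2-fold and 85% of 100 changed 4-fold with edgeR, with 6 false calls among 134. DESeq2 1.42.0 made 30 false calls among 181, a share of 16.6%, and limma-voom 8 among 132. For the interaction edgeR returned 27% at 2-fold and 65% at 4-fold, with 1 false call among 93. For diet in WT mice it returned 58% and 82%, with 5 false calls among 145, while DESeq2 made 33 among 191 (17.3%) and limma-voom 3 among 139. In these simulations genes were drawn independently, and libraries differed only in their totals and the changed genes. The deposited libraries also differ in other ways, so these shares need not hold for them.

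Alternatives fixed before the data were examined were RLE scaling, DESeq2, limma-voom with library weights, no filter and a stricter filter on low counts, transcript length offsets, a model of only the groups compared, and leaving out each mouse in turn. Added after seeing the data were fits without mice 4 and 20 (16829 genes), without 4 and 38, without 4, 20 and 38, and without 31 and 32. Also added were a term for the series of mouse numbers, each series alone, 1 surrogate variable (sva 3.50.0) and libraries thinned to the lowest total. For the correlation of knockout and diet effects, the series coefficient of a fit with the 4 groups was also taken off each gene, in observed and simulated libraries alike. The library check, also added, concerns mice 4 and 20. In it, genes whose log2 CPM separated the other KO from the other WT mice without overlap, with mean log2 values over 1 apart, were chosen without mice 4, 20 and 38 and without the mouse being placed, and each library was set on the KO or WT side of the midpoint. Splits of the libraries were drawn 100 per comparison, the labelled one included, first freely and then, added later, only within mice 1 to 18 and within mice 20 to 40. On simulated libraries the library check put mouse 4 on the KO side at 9.25% with labels right and 78.8% with mice 4 and 20 exchanged, and mouse 20 at 77.5% and 10%. Figures were drawn with matplotlib 3.10.9.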

Results

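Klotho is a membrane protein that serves as a coreceptor for the hormone FGF23, and mice without it develop high serum phosphate and calcified arteries. RNA was sequenced from the thoracic aorta of 12 WT and 12 KO mice, each genotype split evenly between a minimal and a high magnesium diet, to ask how the diet changes aortic expression in either genotype. WT mice on minimal magnesium (6 mice) served as the control group, per the series design. Library totals averaged 12917143 ± 2670980 counts (SD, n = 6) in WT mice on minimal magnesium and 15717527 ± 2854948 in WT mice on high magnesium. KO mice averaged 14576872 ± 2260968 on minimal and 12447346 ± 2061065 on high magnesium. Genes with a count numbered between 21149 and 23980 per library.

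The first principal component held 30.4% of the variance and the second 20.7%. On the first, KO mice 35, 36, 37 and 40 on minimal magnesium and KO mice 31 and 32 on high magnesium scored above 56, together with mouse 4, a library labelled WT on minimal magnesium with a score of 73.6. KO mice 11, 12, 13 and 16 on high magnesium scored -49.2, -16.11, 18.97 and -40.71 there. KO mouse 18 on minimal magnesium scored 11.47 and WT mouse 38 scored 33.27, so the first component did not separate the genotypes. Mouse 20, labelled KO on minimal magnesium, scored 0.14 on the first component and 69.0 on the second, nearest on the second to mouse 38 (WT, minimal magnesium, 91.8).

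**Figure D1:**
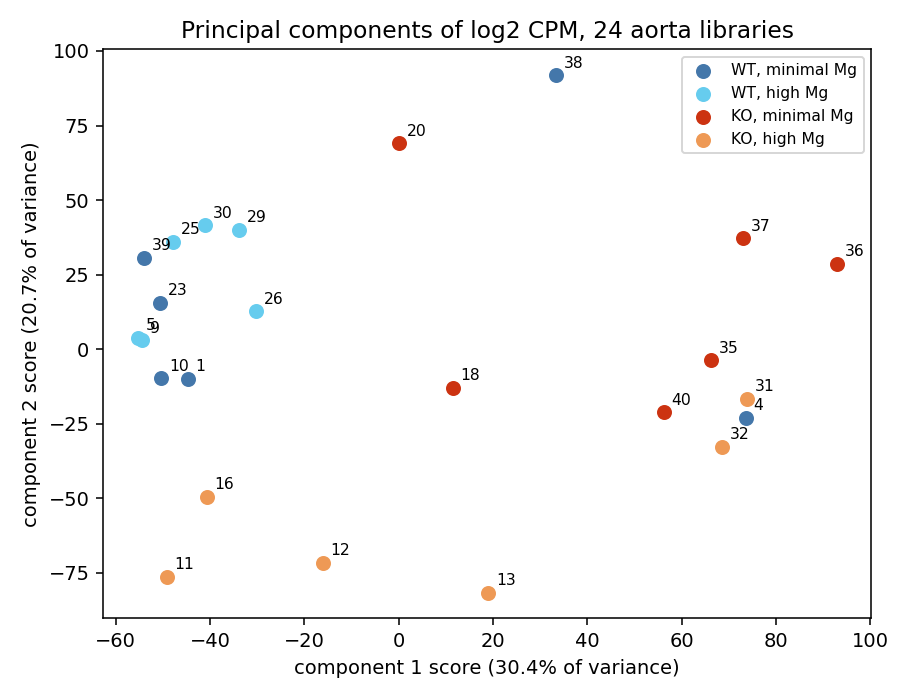
Scores of the 24 libraries on the first 2 principal components of log2 CPM (x axis 30.4% and y axis 20.7% of the variance); each point is a mouse, numbered and coloured by its labelled group. Mouse 4, labelled WT, scores 73.63 on the first component, and mouse 20, labelled KO, scores 0.14.

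The identifiers could not be paired with symbols, so the transcript of Klotho itself gave no check of the genotype labels. Genes that separated the other KO from the other WT mice were read in its place. At 304 such genes (176 higher and 128 lower in KO mice), the library labelled WT of mouse 4 lay on the KO side at 95.7%, and the library labelled KO of mouse 20 lay there at 7.57%. The other 11 KO mice lay on the KO side at 74.6% to 97.7% of 304 to 382 genes, and 10 other WT mice at 1.62% to 25.7%. Mouse 38, also kept out of the choice of genes, lay there at 12.8%. The difference between genotypes at the 304 genes correlated at r = 0.967 with their loading on the first component, so this reading is not independent of the scores above. Labels were kept as deposited, and the total of genes called in each comparison is also given without mice 4 and 20, an alternative added after the libraries were seen.

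**Figure D2:**
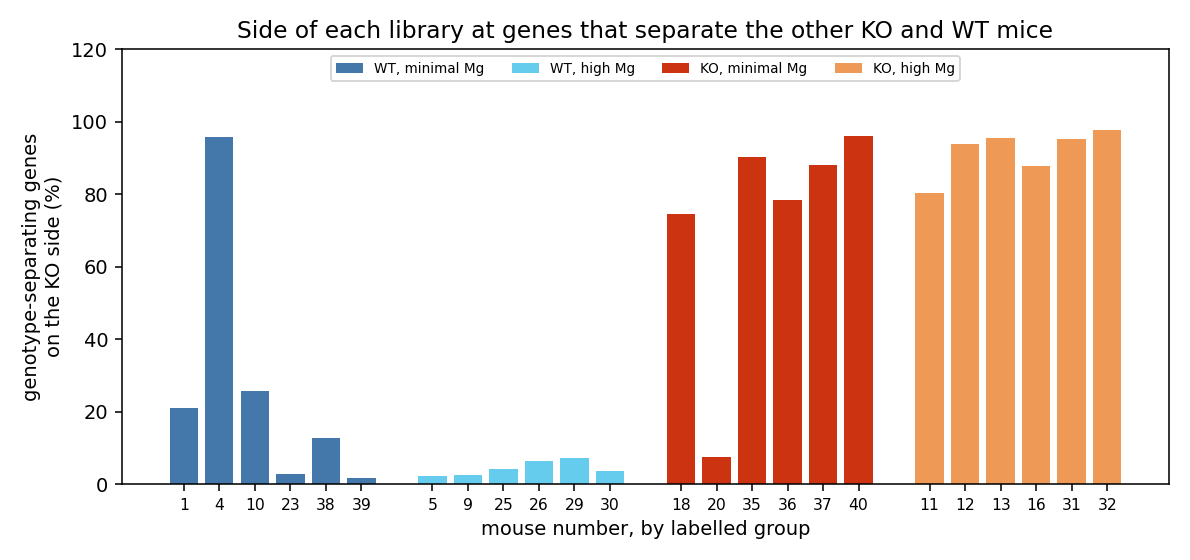
Share of genotype-separating genes at which each library lay on the KO side (y axis, percent), for 24 mice ordered by labelled group (x axis, mouse number). Mouse 4 (labelled WT) stands at 95.7% and mouse 20 (labelled KO) at 7.57%, while the lowest other KO mouse stands at 74.6% and the highest other WT mouse at 25.7%.

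On minimal magnesium, 117 genes were higher and 21 lower in mice labelled KO than in mice labelled WT, 138 of 16741 tested, and 94 of these differed more than 2-fold. MGP_C57BL6NJ_G0022218 rose from 1.97 ± 0.46 CPM in WT mice to 18.0 ± 8.82 CPM in KO mice (SD, n = 6 per group), a log2 fold change of 3.19 ± 0.40 (SE, edgeR adjusted p = 0.00108). It was higher in 5 of 6 KO mice than in any WT mouse, and mouse 20 stood at 2.06 CPM. MGP_C57BL6NJ_G0031269 rose from 6.15 ± 3.61 to 32.6 ± 16.0 CPM, a log2 fold change of 2.40 ± 0.37 (adjusted p = 0.00673), with mouse 4 at 13.1 and mouse 20 at 8.63 CPM. Leaving out these 2 mice gave log2 fold changes of 3.56 ± 0.28 and 3 ± 0.27 for the 2 identifiers. Of the 117 genes that rose, 16 also rose in KO mice on high magnesium, against 19 for independent lists, and of the 21 that fell, 11 also fell, against 3.53. These overlaps do not allow for the series of mouse numbers, unevenly spread over the groups. Without mice 4 and 20 the count was 4061 (2291 higher, 1770 lower), 1961 of them past 2-fold, and all 138 genes remained called with the same sign. Then 953 risers also rose and 864 fallers also fell on high magnesium, against 415 and 326 for independent lists. These 2 mice were picked for going against the genotype difference of the other mice, both diets included. A higher overlap without them is therefore expected from that choice alone, by an amount that was not measured. Without mouse 4 alone the count was 2171, without mouse 20 alone 1523, and without mouse 1, 10, 36 or 40 it was 5. It was 11 without mouse 23, 9 without 39, 22 without 35 and 20 without 37, and 37 genes were called with a term for the series of mouse numbers (32 of them among the 138) and 3 with 1 surrogate variable. Among mice 20 to 40 alone the count was 772, and with the series term and without mice 4 and 20 it was 4781. A model of only these 12 libraries called 0, with 818 by DESeq2 and 5531 by limma-voom with library weights over all 24.

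In KO mice, 1960 genes were higher and 2214 lower on high than on minimal magnesium, 4174 in all. Of these, 536 rose and 1113 fell more than 2-fold. MGP_C57BL6NJ_G0031862 fell from 223 ± 57.3 CPM in KO mice on minimal magnesium to 57.5 ± 9.42 CPM on high magnesium, 3.87-fold (log2 fold change -1.95 ± 0.15 SE, adjusted p = 1.25e-07). MGP_C57BL6NJ_G0028088 fell from 94.8 ± 9.60 to 28.8 ± 5.72 CPM, 3.29-fold (adjusted p = 1.34e-07). For both, every KO mouse on high magnesium lay below every KO mouse on minimal magnesium. MGP_C57BL6NJ_G0022218 fell 7.8-fold, to 2.29 ± 0.97 CPM (adjusted p = 2.83e-05), and MGP_C57BL6NJ_G0031269 fell 5.33-fold, to 6.09 ± 1.91 CPM (adjusted p = 8.76e-05). These 2 were chosen for high values in the same 6 KO libraries on minimal magnesium, which favours a fall. Without mice 4 and 20, 4249 genes were called, 3654 of them among the 4174. Mice 20 to 40 make up 5 of 6 KO mice on minimal and 2 of 6 on high magnesium, so diet and series were partly confounded. With a term for the series of mouse numbers 3251 genes were called, 2855 of them among the 4174. Among mice 20 to 40 the count was 2135, and among mice 1 to 18, with 1 KO mouse on minimal magnesium, it was 86.

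High magnesium in WT mice changed no gene past the threshold. At an unadjusted p under 0.05 there were 1319 genes, and the smallest adjusted p of edgeR was 0.311. DESeq2 called 231 genes, 226 of them lower on high magnesium, and limma-voom with library weights called 0. MGP_C57BL6NJ_G0031862 stood at 118 ± 16.8 CPM on minimal and 141 ± 13.9 CPM on high magnesium, and MGP_C57BL6NJ_G0028088 at 72.2 ± 8.52 and 94.9 ± 18.9 CPM (n = 6 per group), with adjusted p of 0.694 and 0.382. Without mice 4 and 20 the count was again 0, with 1103 genes at an unadjusted p under 0.05.

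The diet effect itself differed between genotypes at 1830 genes, more positive in KO than in WT mice at 785 and more negative at 1045. The difference of log2 fold changes was -3.65 ± 0.55 (SE) for MGP_C57BL6NJ_G0022218 (adjusted p = 0.000308) and -2.44 ± 0.50 for MGP_C57BL6NJ_G0031269 (adjusted p = 0.00374), or -4.03 ± 0.36 and -3.04 ± 0.35 without mice 4 and 20. It was -2.21 ± 0.21 for MGP_C57BL6NJ_G0031862 (adjusted p = 2.04e-06) and -2.11 ± 0.19 for MGP_C57BL6NJ_G0028088 (adjusted p = 1.76e-06). Among mice 20 to 40 the first 2 identifiers were no longer called, at -3.83 and -2.53 (edgeR adjusted p = 0.0513 and 0.074). The last 2 stayed called there (adjusted p = 0.00596 and 0.000615). The balance of directions depended on the setting, with 1960 more positive and 1560 more negative without mice 31 and 32, 2129 and 2123 with limma-voom weights, and 304 and 860 without a filter on low counts. Without mice 4 and 20, 1863 genes were called (578 more positive, 1285 more negative), 1343 of them among the 1830. The count was 1057 with a term for the series of mouse numbers, 397 among mice 20 to 40 and 0 among mice 1 to 18, and it was 2789 without mouse 31 and 1209 without mouse 36.

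**Figure D3:**
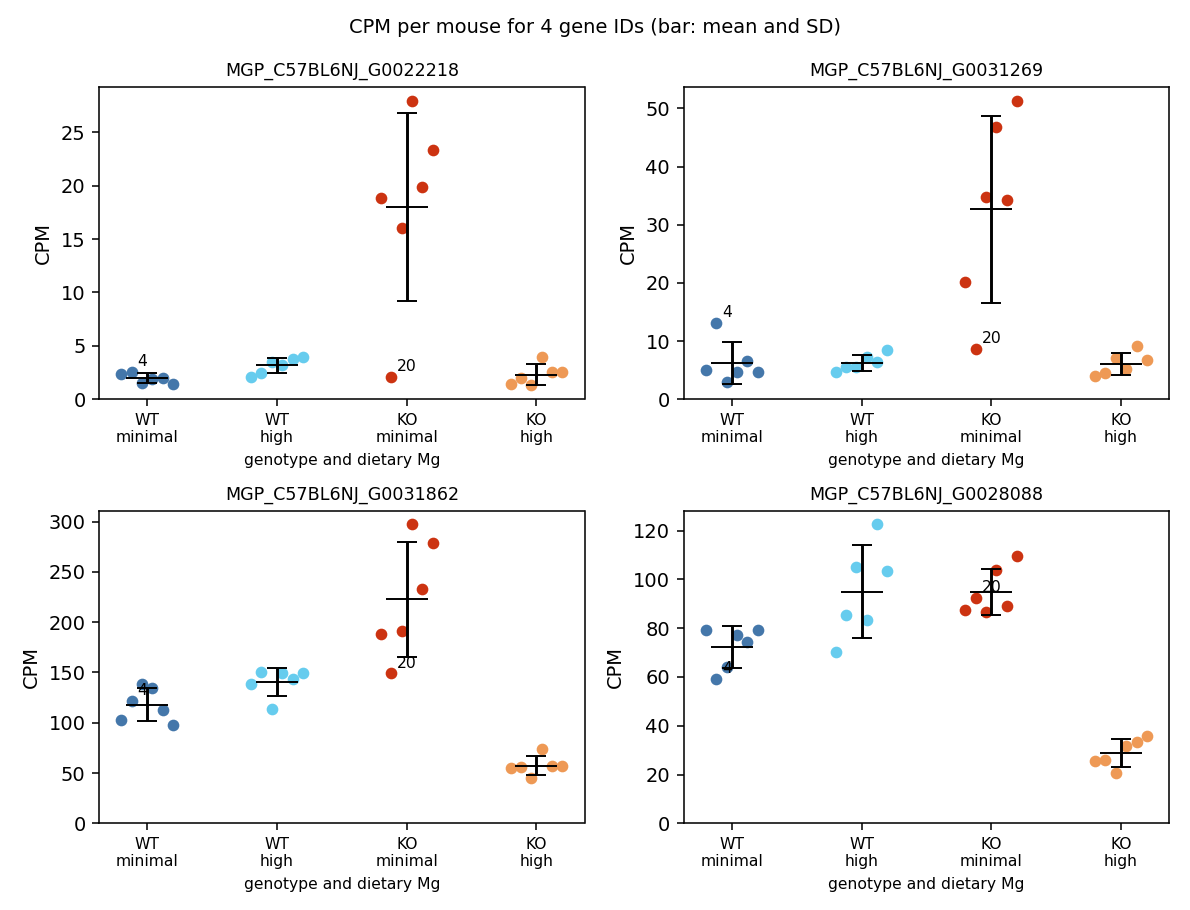
CPM per mouse (y axes, linear from 0) for 4 gene identifiers in the 4 groups (x axes); points are mice, bars the mean and SD of 6, and mice 4 and 20 are numbered. MGP_C57BL6NJ_G0022218 averages 18.0 CPM in KO mice on minimal magnesium and 2.29 CPM in KO mice on high magnesium, and MGP_C57BL6NJ_G0031862 averages 223 and 57.5 CPM.

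On high magnesium, KO mice differed from WT mice at 5538 genes, 2721 higher and 2817 lower, with 1143 and 1023 of these past 2-fold. MGP_C57BL6NJ_G0028088 was 3.29-fold lower in KO mice (log2 fold change -1.72 ± 0.14 SE, adjusted p = 2.6e-07) and MGP_C57BL6NJ_G0031862 was 2.45-fold lower (adjusted p = 4.94e-06). These 2 were chosen for a fall in the same 6 KO libraries on high magnesium, which favours a lower value in KO mice. MGP_C57BL6NJ_G0022218 and MGP_C57BL6NJ_G0031269, both higher in KO mice on minimal magnesium, did not pass on high magnesium (log2 fold changes -0.46 ± 0.38 and -0.04 ± 0.35, adjusted p = 0.367 and 0.945). Without mice 4 and 20, neither of which is in these groups, the shared model called 6146 genes, 5498 of them among the 5538. Among mice 1 to 18 the count was 1072.

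KO mice on high magnesium differed from the control group at 4215 genes, 2001 higher and 2214 lower, and at 5405 without mice 4 and 20. A set of 2101 genes stood apart in KO mice on high magnesium from all 3 other groups, 1066 higher and 1035 lower, and 1917 without mice 4 and 20. Being chosen on these libraries, the set is a description of them. The higher genes held 9.24 ± 0.808% of counts in KO mice on high magnesium against 5.70 ± 0.897% in KO mice on minimal magnesium, 4.80 ± 0.901% in control mice and 4.43 ± 0.17% in WT mice on high magnesium (SD, n = 6). The lower genes held 5.17 ± 1.11% against 11.7 ± 0.811%, 9.53 ± 2.15% and 11.5 ± 2.44% in the same order. A model of only the 12 libraries compared called 2371 genes.

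**Figure D4:**
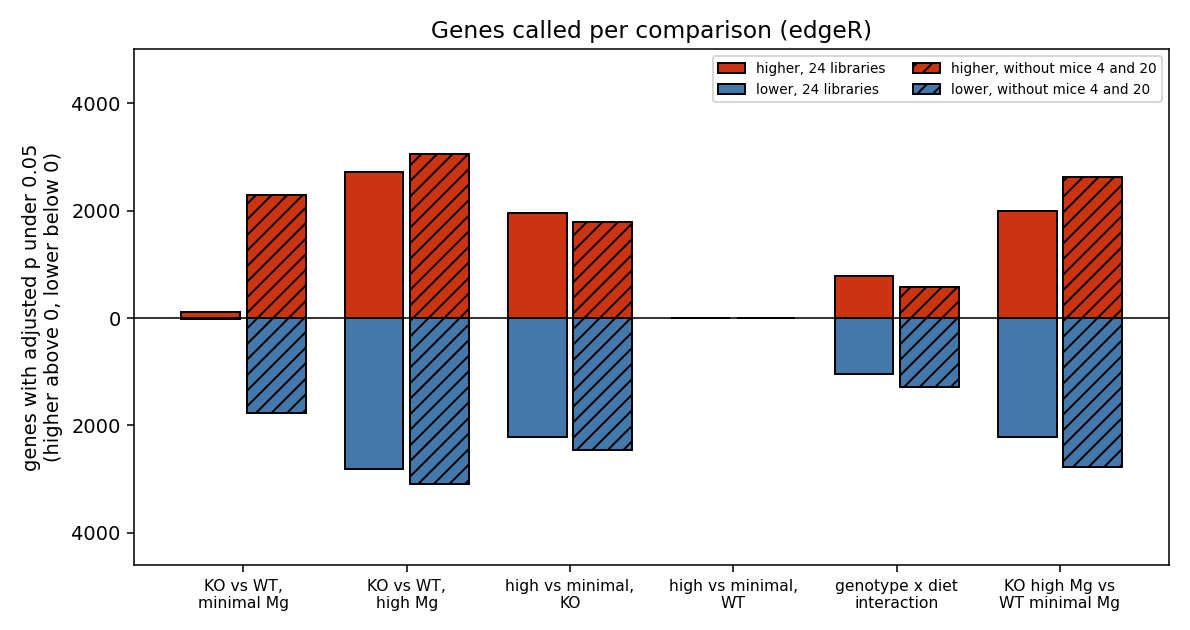
Genes called by edgeR at an adjusted p under 0.05 in 6 comparisons (x axis), higher above 0 and lower below 0 (y axis, number of genes); plain bars use 24 libraries and hatched bars leave out mice 4 and 20. For KO against WT on minimal magnesium the bars hold 138 and 4061 genes, and for diet in WT mice both hold 0.

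Whether the diet moved genes against the direction of the knockout was read across genes, which are not independent replicates. The log2 fold change of KO against WT mice on minimal magnesium correlated with that of the diet in KO mice at r = -0.489, with a covariance of -0.213. Both hold the same KO libraries with opposite sign, and simulated libraries with no effect gave r = -0.496 and a covariance of -0.0753, a difference in covariance of -0.138. With the KO libraries split so that the comparisons shared none, r averaged -0.318 over 20 splits, from -0.535 to 0.00645, and the covariance averaged -0.147. Neither value allows for the series of mouse numbers, unevenly spread over these groups (mice 20 to 40 make up 5 of 6 KO mice on minimal, 2 of 6 KO mice on high magnesium and 3 of 6 controls), which alone gives a negative covariance. With the series removed, r was -0.377 and the covariance -0.135, against -0.531 and -0.0769 with no effect, a difference of -0.0578. With split libraries r then averaged -0.195, from -0.401 to 0.0965, against -0.0697 with no effect. Of the 117 genes that rose in KO mice on minimal magnesium, 94 fell with the diet, against 15.5 for independent lists and 73.5 (59 to 82) for lists of equal length from simulated libraries with no effect. Of the 21 that fell, 3 rose, against 2.46 and 14 (10 to 19). The simulated lists, here and below, are the top genes of libraries without any effect, picked partly for noise in the shared KO libraries. The observed lists are edgeR calls and may hold real effects, which that noise does not reverse. A count below the simulated range therefore does not show that fewer genes reversed than without an effect. Genes were also simulated independently, whereas real genes vary together, so the simulated ranges are too narrow for real libraries. A count above its range therefore does not show a reversal either. Without mice 4 and 20, r was -0.526 with shared libraries, against -0.52 with no effect, and the covariance -0.326, against -0.081. With split libraries r was then -0.387, against -0.00367, values that again leave out the series. With the series removed as well, r was -0.413 with shared and -0.268 with split libraries, against -0.525 and -0.0452. The choice of these 2 mice bears on the genotype effect in all of these values, and the simulations leave it out. Then 1040 of 2291 risers fell with the diet, against 335 for independent lists and 929 (885 to 979) with no effect, and 311 of 1770 fallers rose, against 188 and 622 (580 to 671). With all 24 libraries and a term for the series, 28 of 33 risers fell, against 3.57 and 21.8 (14 to 29), and 0 of 4 fallers rose, against 0.344 and 2.9 (1 to 4). With that term and without the 2 mice these were 978 of 2516 risers, against 327 and 931 (894 to 973), and 256 of 2265 fallers, against 196 and 652 (611 to 694).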

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

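The tests of mice 4 and 20, of the series of mouse numbers, of depth and of library totals were chosen after the results were seen, as was the test of splits for KO against WT on minimal magnesium. The other tests of free splits were fixed before their results were seen. Splits within the series were added later, with their limit set before their counts were seen.

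Mice 4 and 20 lay with the genotype opposite to their labels. Low depth is argued against, since the library with the lowest total, mouse 12, lay with its own genotype at 93.9% of genes and mouse 20 had a total of 17833156 counts. The main axis of variation within groups, which a varying mix of tissue could produce, was also removed. With it removed, mouse 4 lay on the KO side at 95.8% of 448 genes and mouse 20 at 5.58%. The axis was estimated without mice 4 and 20 and held 27.4% of the variance within groups. The way these mice depart from their groups need not lie on it, so a varying mix of tissue stays open as a cause. Neither the reading before nor that after the removal of this axis is independent of the first principal component. The difference between genotypes correlated with the loading of that component at r = 0.967 before and 0.893 after. An exchange of the 2 samples or labels remains a candidate explanation, since mouse 4 lay on the KO side at 95.7% and mouse 20 on the WT side, each within the range of the other genotype. At genes that set KO mice on minimal magnesium apart, mouse 4 lay on their side at 83.2%, within the 65.7% to 98.8% of the other KO mice on that diet, and mouse 20 at 9.29%, within the 2.21% to 17.9% of 4 other WT mice. At 17 genes with a gap of over 1 log2 unit between genotypes mouse 4 lay on the KO side at 16 and mouse 20 at 1. Some values do not follow it. MGP_C57BL6NJ_G0022218 stood at 2.59 CPM in mouse 4 where the other 5 KO mice on minimal magnesium averaged 21.2 ± 4.57, although that gene was chosen with mouse 4 counted as WT. Mouse 20 does follow an exchange at this gene, with 2.06 CPM against 1.38 to 2.36 in the other WT mice on that diet. MGP_C57BL6NJ_G0031862, chosen on the diet in KO mice, stood at 121.5 CPM in mouse 4 and 149.1 in mouse 20, with 187.8 to 297.4 in these 5 and 98.17 to 139 in the other WT mice on minimal magnesium. MGP_C57BL6NJ_G0028088, chosen likewise, stood at 59.03 CPM in mouse 4 and 92.33 in mouse 20, with 86.49 to 109.4 in these 5 KO and 64.16 to 79.23 in these WT mice. At genes that set KO mice on high magnesium apart, mouse 4 lay on their side at 35.6%, above the 4.19% to 31% of the other KO mice and the 1.1% to 13.6% of 4 other WT mice on minimal magnesium, so that value fits neither group, while mouse 20 lay there at 1.27%, within the range of these WT mice.

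Few genes were called between KO and WT mice on minimal magnesium. The series of mouse numbers stays open as a part of it: a term for the series gave 37 genes, fewer than 138, but mice 20 to 40 alone gave 772. Mouse 4 is not among these, and leaving out mouse 4 alone gave 2171. The 772 genes therefore cannot tell the series from the absence of that library. Whether libraries out of place account for the low count stays open. The count was 4061 without mice 4 and 20, but these mice were picked because they lay with the other genotype. A rise without them is expected from that choice alone, by an amount that was not measured. Chance is not excluded for the 138 genes, since 11 of 100 splits of the 12 libraries gave as many and the highest of the others gave 1592, several times the real count, which points to a structure of these libraries that the labels do not follow. That split set mice 4 and 10 with KO and mice 20 and 37 with WT mice, although mice 10 and 37 lay with their labelled genotype (25.7% and 88.1% on the KO side). Within the series, 11 of 100 splits gave as many and the highest of the others gave 1361. With mice 4 and 20 left out, 1 of 100 splits reached 4061, the real one, with 2925 as the highest of the others and 665 within the series, but the choice of these mice favours the labelled split, so this decides nothing about chance.

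The diet effect differed between genotypes at 1830 genes, a difference tested by the interaction itself. Unequal library totals are argued against as the whole cause by 1757 genes with libraries thinned to the lowest total. Mice 4 and 20 are argued against as the whole cause by 1343 of the 1830 genes, which stayed called with the same sign without them. The total without them was 1863, but the interaction holds the genotype difference on minimal magnesium. These mice were picked for going against that difference, so their choice bears on the total by an amount that was not measured. The series of mouse numbers is argued against as the whole cause by 1057 genes with its term. Mice 20 to 40 gave 397 genes, but hold only 2 KO mice on high and 3 WT mice on minimal magnesium. Fewer mice alone could lower that count, so whether the series accounts for part of the 1830 stays open. Of 100 splits of diet within genotype, 1 gave as many genes, the real one, and the highest of the others gave 1124. Within the series, 2 of 100 gave as many, the real one and 1 with 1831 genes, which kept the labels of all KO mice and exchanged WT mice 10 and 38 with 5 and 30. These splits exchange diet labels in KO as well as in WT mice, so they also undo the diet effect in KO mice. Fewer than 5 of 100 in both argues only against no diet effect in either genotype. For a difference between genotypes the splits decide nothing about chance, and the count alone does not set the real diet labels of WT mice apart. A different mix of tissue in KO mice on high magnesium was not tested, since marker genes could not be named. The interaction is the test made here of a response to dietary magnesium that depends on Klotho, which stays open as a hypothesis.

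All 4 printed identifiers also differed in diet effect between genotypes, with interaction log2 fold changes of -3.65 for MGP_C57BL6NJ_G0022218, -2.44 for MGP_C57BL6NJ_G0031269, -2.21 for MGP_C57BL6NJ_G0031862 and -2.11 for MGP_C57BL6NJ_G0028088. They were chosen on KO libraries that the interaction shares, so this is no separate evidence. In 36 tests for a sample far from its group, 2 stood out, against 1.8 by chance. MGP_C57BL6NJ_G0031269 stood at 13.12 CPM in mouse 4 against 2.91 to 6.65 CPM in the other 5 mice labelled WT on minimal magnesium. MGP_C57BL6NJ_G0031862 stood at 113.9 CPM in mouse 25 against 138.2 to 150.0 CPM in the other WT mice on high magnesium.

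In 3 of the remaining comparisons, which share the KO libraries on high magnesium, chance is argued against but not excluded by 100 splits. For KO against WT on high magnesium 1 of 100 splits, the real one, reached 5538 genes. The highest of the others gave 3147, with mice 9 and 31 exchanged. For the diet in KO mice 1 of 100 reached 4174, with 2021 as the highest of the others. For KO mice on high magnesium against the control group 1 of 100 reached 4215. The highest of the others there gave 3734, a split that differs from the labels by the exchange of mice 4 and 11. Within the series, 1 of 100 splits, the real one, reached each of these 3 counts, and the highest of the others gave 1400, 3040 and 3734. For the diet in WT mice the real count was 0, which all 100 splits reached. The highest of the others there, 3285 genes, set mice 1, 4, 5, 9, 10 and 23 against the rest, which follows the series of mouse numbers except for mouse 23, and the fit with a term for the series called 0 genes. Within the series the highest of the others gave 6.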

How the results depend on the processing

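Settings that leave out named mice or mouse numbers, the series term, the surrogate variable and thinning were chosen after seeing the data. Counts for KO against WT on high magnesium, the diet in KO mice and KO mice on high magnesium against controls stayed within 1.5 times in 16, 15 and 14 of 17 settings. The exceptions were mice 1 to 18 alone (1072, 86 and 663 genes), mice 20 to 40 alone for the diet in KO mice (2135), and, for KO on high magnesium against controls, only the groups compared (2371) and the series term without mice 4 and 20 (6541). With 1 mouse left out these counts ran from 4668 to 5719, 3000 to 5087 and 3366 to 5170. The diet in WT mice called 0 genes in 16 of 17 settings and with any of its mice left out, and 231 by DESeq2. In simulation of this comparison DESeq2 made false calls at 17.3%, but on 16741 filtered genes, against 31121 genes here. That share therefore does not tell how many of the 231 calls are false.

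The interaction moved to 4252 genes with limma-voom weights, 1164 without a filter on low counts (more genes tested), 3520 without mice 31 and 32, 1057 with the series term, 397 among mice 20 to 40 and 0 among mice 1 to 18 (1 KO mouse on minimal magnesium, assumed to vary like the others). With 1 mouse left out it ran from 1209 to 2789. KO against WT on minimal magnesium stayed within 1.5 times of 138 in 2 of 17 settings, RLE scaling and the stricter filter. It gave 818 genes with DESeq2, 5531 with limma-voom weights, lowest for mice 4 and 20 (0.32 and 0.366), 57 without a filter, 79 with length offsets, 0 with only its groups, 84 with libraries thinned to the lowest total, 37 with the series term, 3 with 1 surrogate variable, 772 among mice 20 to 40 and 0 among mice 1 to 18. It gave 4061 without mice 4 and 20, 4781 with the series term as well, 4885 without 4, 20 and 38, 3295 without 4 and 38, 215 without 31 and 32, and 5 to 2171 with 1 mouse left out. Apart from the fits with fewer mice or more genes, the cause was not tested.

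The correlation between knockout and diet effects was -0.489 with shared libraries, where no effect gave -0.496. With split libraries it was -0.318, and -0.195 with the series removed as well (no effect -0.0697), or -0.268 with mice 4 and 20 also left out (no effect -0.0452). Shared and split values have different no-effect values and are not to be ranked. Of 740 alternatives for the printed identifiers, 479 concern called values, of which 465 kept call and direction and 14 lost the call. Of the 261 for values not called, 259 stayed so, 29 of them with the sign changed, all of MGP_C57BL6NJ_G0031269 and between -0.492 and 0.555. Of the others 1 gained a call and 1 reversed: MGP_C57BL6NJ_G0031269 in KO mice on high magnesium against controls, not called at -0.01, was 0.522 (adjusted p = 0.036) with the series term without mice 4 and 20. No paired analysis was possible because each mouse number in the labels occurs in 1 group only. Covariates for sex, fat and muscle and the tests of gene lists were not run, since they need symbols. In simulation with the fitted spread and 6 mice per group, 43% of 2-fold changes between KO and WT mice on minimal magnesium were called. Genes were drawn independently there, so that share need not hold for the deposited libraries.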

Other observations

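Mice numbered 1 to 18 (10 libraries) had totals of 9947302 to 13244580 counts and mice numbered 20 to 40 (14 libraries) 13215958 to 18926675. The labels name no batch or series, and the cut between mice 18 and 20 was set after the data were seen. No other cut was tried. The earlier series held 3 WT and 1 KO mouse on minimal magnesium and 2 WT and 4 KO mice on high magnesium, so the series and the diet of KO mice were partly confounded. With the 4 groups in the model, 5168 of 16741 genes differed between the series, 2746 higher and 2422 lower in the later one.

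Across genes, the knockout effects on both diets correlated at r = 0.294 and the diet effects in both genotypes at r = 0.293, and at 0.450 and 0.250 without mice 4 and 20. None of these values allows for the series of mouse numbers. Mice 20 to 40 make up 3 of 6 WT and 5 of 6 KO mice on minimal magnesium, and 4 of 6 WT and 2 of 6 KO mice on high magnesium. The series thus enters the 2 effects of each pair with opposite sign, which alone lowers r. These pairs of comparisons share no library. Mice 4 and 20 were picked for going against the genotype difference of the other mice. A rise such as that to 0.450 is therefore expected from that choice, by an amount that was not measured.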
